A study of Mus musculus with 4 samples.

How the data were processed

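The series holds 4 arrays of mouse intestinal organoids (Apc fl/fl), 1 each for untreated and 4OHT-treated organoids collected at day 4 and at day 6. Per the labels' protocols, organoids were given 4OHT for 24 h, recovered from Matrigel, and total RNA was extracted on columns. Biotinylated copy RNA was made from 100 ng of total RNA with a 3' in vitro transcription kit, per the labels' protocols. This labelling starts at the poly-A tail, so probe sets read mostly the 3' ends of transcripts. The labels call the 4OHT arrays Apc-deficient. They state no replicate numbers, batches or dates.

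The deposited values are linear probe-set intensities, already summarised to 1 value per probe set and array. The method of background correction, normalization and summarisation is not given in the sources used here. From the values, the percentiles of the arrays of one day nearly coincide while those of the 2 days differ, so the scaling between the days is unknown, as is whether any centring was applied. Intensities ran from 2.73 to 23910.3. All 4 columns were used. No detection calls are used here, and a level filter stands in for them.

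Of 45101 probe sets, 34958 name 1 gene in the platform's annotation, 932 name several and 9211 are not in that annotation. Of those with 1 gene, 34754 matched a current gene record by their gene identifier and no symbol changed. Probe sets with several genes or none, and 64 control probe sets, were left out of the gene table. Each of the 18193 remaining genes was given the probe set with the highest mean over the 4 arrays, and that choice was kept under every alternative except those on probe sets. Keeping it was decided after seeing that Trpm7 turned its direction over time when quantile normalization also chose the probe sets anew. Values were taken as deposited and moved to log2(intensity + 16). For 12 named genes (Aen, Apc, Cd4, Cd8a, Cdk6, Cdt1, Lss, Mdm2, Nkd1, Nolc1, Pdk1 and Rassf10), other probe sets past the level filter below did not all give the same direction with 4OHT on both days; each value printed is that of the brightest. A gene passed the level filter where its highest value on the 4 arrays was at or above the median of all values, an intensity of 20.9, which 13192 genes did.

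Contrasts were 4OHT against untreated at day 4 and at day 6, day 6 against day 4 in each arm, and the difference between the days in the 4OHT effect. Each sets 1 array against 1, so a gene was counted as higher or lower at a difference of at least 2-fold, with no p-value. The contrasts of the 2 days share no array, nor do those of the 2 arms. The only test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 4 arrays with 4OHT and day as additive terms, Benjamini-Hochberg adjustment over the genes past the level filter, and a threshold of 0.05. Standard errors in the text are from this test, which has 1 residual degree of freedom, 15.2 prior degrees of freedom and a prior SD of 0.215. Its residual error is the difference between the effects of the 2 days, moderated toward a value pooled over genes. "Rose" and "fell" are used for genes past this test. The 4 arrays are not stated to be separate cultures. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

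The test was tested on simulated data made from the real genes' levels, for the 4OHT effect over both days on 13192 genes. It called 73 of 100 genes changed by 1 on the log2 scale, all 100 changed by 2, and 18 of 12992 unchanged genes, so that 9.42% of its 191 calls were false, above the nominal 5%. The simulated noise was independent between genes and arrays, with spreads drawn around a common value, much as the test assumes. It held no difference between whole arrays, such as 3' bias, so these rates need not hold for the real arrays.

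The gene lists, the rule for named genes, the contrasts and most alternatives were fixed before the data were examined. The 20 lists hold 306 entries, of which 274 were measured and 32 are not analysed here, and 1 was found under another name (Irag2 as Lrmp). Lists were described by their median, its percentile among 10000 random lists of the same size drawn from genes in the same of 10 bins of mean level, and counts of members. Named genes were Apc, up to 4 members of each list with the largest smaller difference of the 2 days in the same direction, the 10 genes higher and 10 lower with 4OHT by the same measure over all genes, and 5 higher and 5 lower for day 6 against day 4. Predicted gene models and genes with clone names, such as those ending in Rik, were passed over. This left out 1 gene, 2610528A11Rik, from those lower with 4OHT. Genes outside this rule are marked in the text as named after their values were seen.

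Alternatives were no level filter, the filter on the mean or at the 75th percentile, the mean of all probe sets of a gene, median centring, quantile normalization, pseudocounts of 1 and 64, thresholds of 1.5-fold and 3-fold, an adjusted p of 0.1, no day term, eBayes with trend and robust, and leaving out each array. Leaving out probe sets of the _x_at and _s_at kinds, which can bind more than 1 transcript, was added after seeing the data.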

Results

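Gene expression was measured in mouse intestinal organoids, epithelial cultures grown in Matrigel, whose Apc alleles were floxed (Apc fl/fl). Apc encodes a scaffold of the complex that marks beta-catenin for degradation, and its loss activates Wnt signalling. Organoids were given 4-hydroxytamoxifen (4OHT) for 24 h to induce recombination of Apc, or were left untreated, and were collected at day 4 or day 6. Each of the 4 groups (untreated at day 4, 4OHT at day 4, untreated at day 6, 4OHT at day 6) was represented by 1 expression array, so no group had replicates and the number of arrays limits the precision. Each array gave 45101 probe-set intensities. Their median was 22.0 in the untreated and 21.9 in the 4OHT array of day 4, and 19.3 and 19.5 at day 6. The range between the 5th and 95th percentiles was narrower at day 4 (5.77 and 5.90 on the log2 scale, untreated and 4OHT) than at day 6 (6.89 and 6.73). How the arrays of the different days were scaled to each other is not known, and no 4OHT-treated organoids without the floxed allele are among the 4 arrays. Differences below are on the log2(intensity + 16) scale, which understates the change of dim genes. Values of the hybridization, poly-A, Actb and Gapdh control probe sets are log2 intensities with nothing added.

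**Figure D1:**
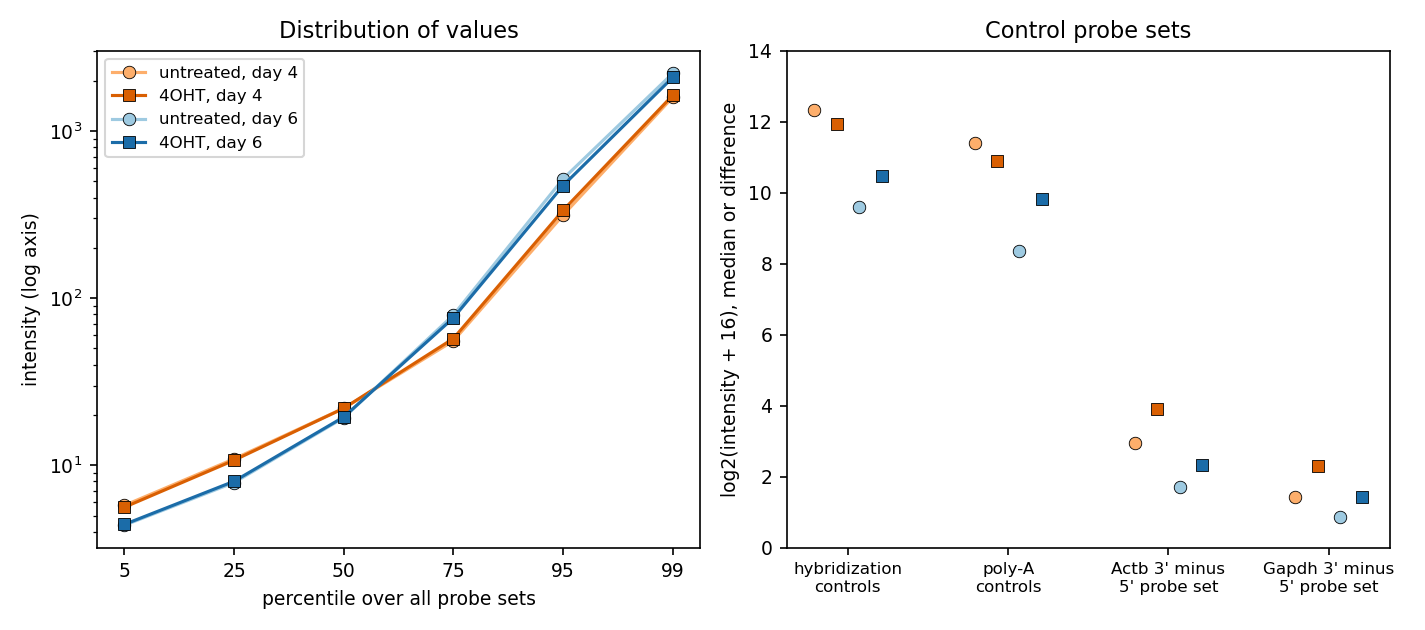
Left, intensity (log axis) at 6 percentiles over all probe sets of each array. Right, the median log2 intensity of the spiked hybridization and poly-A control probe sets, 1 point per array. Beside them is the log2 difference between the 3' and 5' control probe sets of Actb and Gapdh. The + 16 of the right axis label does not apply to these values. The curves of the arrays of a day nearly coincide, and the spiked controls were brighter at day 4 than at day 6. The 3' minus 5' differences were larger on the 4OHT array of each day, and larger at day 4 within each arm.

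Apc itself was read by 4 probe sets, which did not move together. The brightest of them was higher on the 4OHT array on both days, by 0.77 at day 4 and by 0.68 at day 6. It did not pass the test over both days (0.73 ± 0.21, SE, adjusted p = 0.077). Another probe set differed by -0.40 at day 4 and by 0.34 at day 6. The part of the gene removed by recombination is not given in the sources used here and the arrays read the 3' ends of transcripts, so these values check neither the labels nor the recombination.

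The comparison of 4OHT-treated with untreated organoids asked what changed after induced recombination of Apc. Clu, which encodes the secreted chaperone clusterin, rose by 2.11 ± 0.21 (SE), a difference of 3.74-fold at day 4 and 5.01-fold at day 6. Mmp7, a matrix metalloproteinase made by Paneth cells, rose by 2.13 ± 0.25, and Atg9b, an autophagy gene, by 2.19 ± 0.21. The other 7 genes with the largest differences upward on both days also rose, by 1.34 to 1.54. They were the matrix protein gene Thbs1, the interferon-induced membrane protein gene Ifitm3, Rassf10, the tubulin genes Tuba1a and Tubb2b, Ecscr, and the hyaluronan receptor gene Cd44. Tuba1a was read by only 1 probe set, of the _x_at kind, which can bind more than 1 transcript. Leaving out such probe sets therefore could not check it. The 10 genes with the largest differences downward on both days all fell. Ces2a, a carboxylesterase, fell by 2.62 ± 0.27, and the mucosal glycoprotein gene Dmbt1 fell by 2.90 ± 0.32, from an intensity of 169 to 33.5 at day 4 and from 1097 to 58.9 at day 6. The sulfotransferase gene Sult1d1 fell by 2.36 ± 0.21, and Bcl2l15 fell by 2.52 ± 0.22. The alcohol dehydrogenase gene Adh6a fell by 2.42 ± 0.24, and the gluconeogenesis enzyme gene Fbp1 fell by 2.19 ± 0.23. Apoa4, Cyp2s1, Cyp4f14 and Acaa1b fell by 1.87 to 2.06. The lowest adjusted p among these 20 genes was 2.93e-05 (Bcl2l15 and Sult1d1) and the highest 0.00139 (Tubb2b). These genes were picked by their differences on the same arrays, so passing the test is not separate support.

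**Figure D2:**
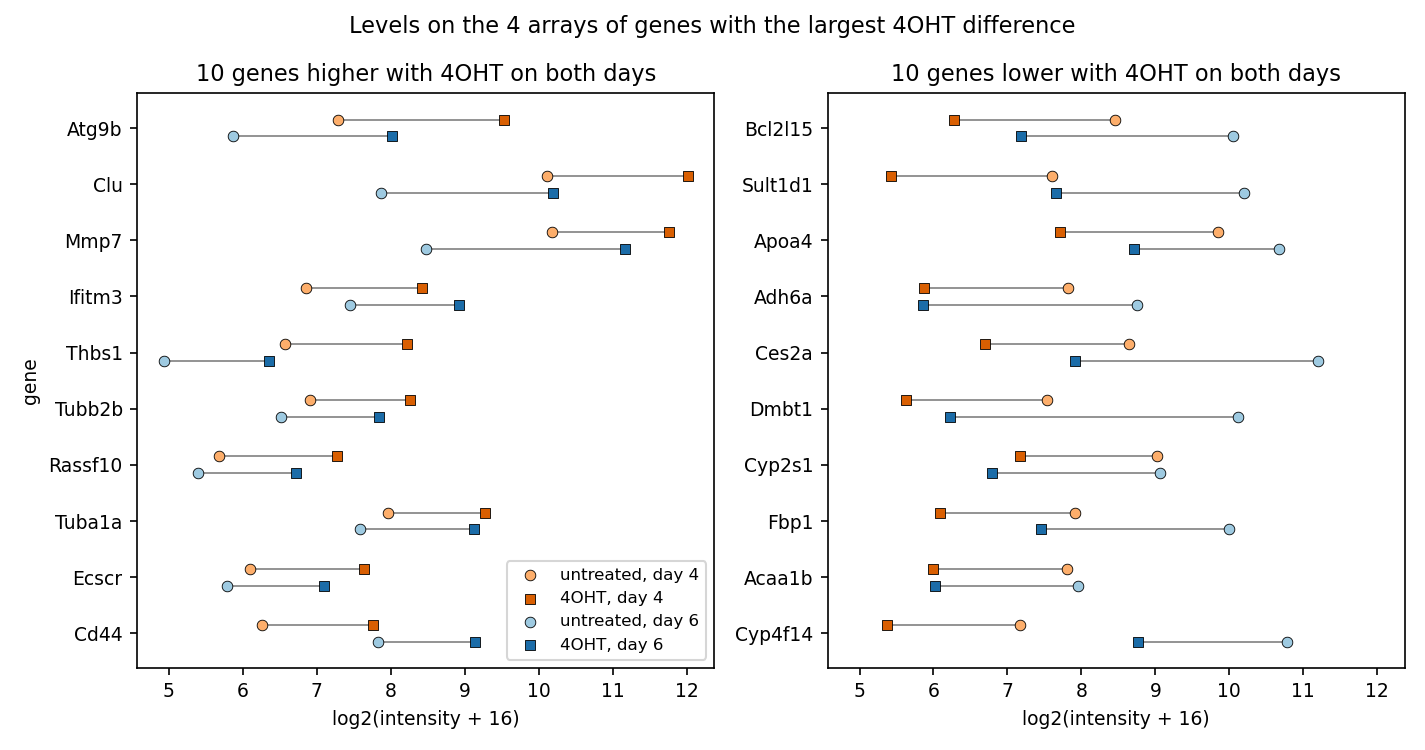
Level, log2(intensity + 16), of the 10 genes with the largest difference upward and the 10 with the largest difference downward on both days, 1 point per array (circles untreated, squares 4OHT; orange day 4, blue day 6), with a line joining the arrays of a day. In every row the square lies on the same side of the circle on both days; Dmbt1 has the widest gap, 14.9-fold at day 6.

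Over 13192 genes past the level filter, 27 were at least 2-fold higher and 105 at least 2-fold lower with 4OHT on both days. Lists independent between the days, with every gene equally likely to pass, would share 1.16 and 4.78. Where dim genes seldom pass, these numbers are too low. Both 4OHT arrays also had the larger 3' minus 5' differences of their day, so the lists need not be independent. No gene passed 2-fold in opposite directions on the 2 days. Limma's test over the 4 arrays, with day as an additive term, called 425 genes at an adjusted p under 0.05, of which 128 rose and 297 fell; 1835 genes had an unadjusted p under 0.05. All 132 genes past 2-fold on both days were among the 425, which is not separate support, since both rules use the same 4 arrays. The residual error of that test is the difference between the effects of the 2 days, with 1 degree of freedom. It is moderated toward a value pooled over genes, with 15.2 prior degrees of freedom. The p-values therefore follow mostly the size of the mean difference and only weakly the agreement of the days. Ccn2, for one, passed with differences of 2.20 at day 4 and 0.26 at day 6. The test does not measure the spread between replicate cultures. Its count depends on the settings: no gene passed without the level filter, with a pseudocount of 64 or without the day term, and leaving out single arrays, also with no day term, left 0 to 65 genes.

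Of 23 measured Wnt target genes, 6 rose by the test over all genes (13 adjusted over the list alone), none fell, 14 did not pass and 3 lay under the level filter and were not tested. Cd44 rose by 1.40 ± 0.21, Nkd1, an inhibitor of the pathway that the pathway itself induces, by 1.73 ± 0.28, and Rnf43, a ubiquitin ligase that removes Wnt receptors, by 1.08 ± 0.21. Nkd1 was 5.50-fold higher at day 4 and 2.01-fold at day 6 on its brightest probe set. Of its 2 probe sets past the level filter, only 1 gave the same direction on both days. Axin2, another feedback inhibitor (0.82 ± 0.21), and the transcription factor gene Sox4 (1.02 ± 0.23) rose too and were named after their values were seen. The median difference of the list was 0.31 at day 4 and 0.66 at day 6, above 99.8% and 100% of random lists of genes of like level, and became 0.47 at day 4 over members past the level filter and 0.38 at day 6 with the mean of all probe sets of a gene. Markers of crypt base columnar stem cells had medians of 0.21 and 0.59, at the 85.8th and 100th percentiles; the former was 0.13 after quantile normalization and 0.13 without the _x_at and _s_at probe sets. Of the 13 measured, Smoc2 (0.84 ± 0.21) and the RNA-binding protein gene Msi1 (0.89 ± 0.21) rose, 10 did not pass and 1 was not tested, and adjusted over the list alone 5 rose and 1 fell. Tnfrsf19 (0.76 ± 0.21, adjusted p = 0.066) and Cdk6 (0.64 ± 0.21, adjusted p = 0.13) were higher without passing. Lgr5, Ascl2 and Tnfrsf19 stand in both lists, and Mmp7 also stands among the Paneth cell markers.

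Genes of fetal and regenerating epithelium included 4 that rose among 11 measured, none that fell, 5 not past the test and 2 not tested (5 rose adjusted over the list alone). After Clu, they were Anxa1, which encodes a phospholipid-binding protein (1.29 ± 0.24), the surface glycoprotein gene Msln (1.19 ± 0.24) and the matricellular protein gene Ccn2 (1.23 ± 0.32), named after its values were seen. Ccn2 was 2.20 higher at day 4 and 0.26 higher at day 6. The list's median was 0.43 at day 4 and 0.45 at day 6, and 0.77 and 0.67 over members past the level filter.

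Enterocyte markers were the list with the most members that fell. Of 23 measured, 15 fell, none rose and 8 did not pass (19 fell adjusted over the list alone), with medians of -1.11 at day 4 and -1.26 at day 6, below every random list of the same size and level. The apolipoprotein gene Apoa4 fell by 2.06 ± 0.21, the glucose transporter gene Slc2a2 by 1.74 ± 0.23, the drug-metabolizing enzyme gene Cyp3a11 by 1.75 ± 0.21 and the fatty acid binding protein gene Fabp1 by 1.53 ± 0.21. On the same arrays the signal of Actb fell off toward the 5' end more steeply with 4OHT, the 3' minus 5' difference being 0.94 larger at day 4 and 0.62 larger at day 6, and that of Gapdh 0.87 and 0.56 larger.

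Among secretory lineages, Paneth cell markers held the largest median differences upward. Of the 7 measured (8 others are not analysed here), 5 rose, none fell, 1 did not pass and 1 was not tested (the same counts adjusted over the list alone), with medians of 0.71 and 1.45 (0.94 at day 6 without the _x_at and _s_at probe sets). Ang4, an antimicrobial ribonuclease, rose by 1.97 ± 0.31, and was 2.03-fold higher at day 4 and 7.53-fold at day 6. The lectin gene Itln1 rose by 1.39 ± 0.25 and the phospholipase gene Pla2g2a by 0.82 ± 0.21. Lyz1 rose as well (0.94 ± 0.24, named after its values were seen), but its sequence is close to that of Lyz2 and its probe set may bind both. Goblet cell markers moved both ways. Muc2, the main secreted mucin (0.84 ± 0.21), the transcription factor genes Spdef (1.04 ± 0.22) and Foxa3 (0.99 ± 0.21), and Spink4 (1.06 ± 0.26) rose, while the mucus protein genes Zg16 and Fcgbp fell by 1.36 ± 0.23 and 0.84 ± 0.22, and of the 11 measured 4 did not pass and 1 was not tested (6 rose and 3 fell adjusted over the list alone). The list's medians were 0.42 (0.27 with the mean of all probe sets) and 0.58. Spink4 and Fcgbp were named after their values were seen. Of 19 enteroendocrine markers, the neurotensin gene Nts (0.96 ± 0.21) and the progenitor factor gene Neurog3 (0.82 ± 0.21) rose, 16 did not pass and 1 was not tested (2 rose and 1 fell adjusted over the list alone), with medians of -0.09 and -0.02. The peptide hormone gene Pyy was lower by 0.55 and 0.91 on the days in turn and Isl1 by 0.61 and 0.39, without passing. Of 16 tuft cell markers 14 were tested; none passed over all genes and 2 fell adjusted over the list alone, with medians of -0.20 and -0.04. Rgs13 differed by -0.74 ± 0.21 (adjusted p = 0.078), Alox5ap by -0.69 ± 0.22, Sh2d6 by -0.35 ± 0.21 and Gfi1b by -0.32 ± 0.21. None of 10 Notch pathway and secretory fate genes passed, over all genes or adjusted over the list alone, with medians of 0.19 and 0.04. Hes6 differed by 0.69 ± 0.21, Nrarp by -0.67 ± 0.23, Dll4 by 0.40 ± 0.22 and Atoh1 by 0.23 ± 0.21.

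None of 18 mitosis genes passed the test, over all genes or adjusted over the list alone. Their medians were 0.06 at day 4 and -0.11 at day 6, the former turning to -0.012 after quantile normalization. Cdk1, the kinase that drives entry into mitosis, differed by 0.12 ± 0.21, Ccnb2 by -0.30 ± 0.21, Ube2c by -0.50 ± 0.21 and Nusap1 by -0.64 ± 0.21. DNA replication genes had medians of 0.43 and 0.33, above 99.9% and 99.8% of random lists, with none of 17 past the test over all genes. Adjusted over the list alone 2 rose, the helicase subunit genes Mcm2 (0.66 ± 0.21) and Mcm7 (0.71 ± 0.21), while Cdt1 (0.58 ± 0.21) and Mcm5 (0.52 ± 0.21) did not pass. With the mean of all probe sets of a gene the medians of that list were 0.16, at the 85.0th percentile of random lists, and 0.18. Ribosome biogenesis genes had medians of 0.24 and 0.16 (0.076 at day 6 without the _x_at and _s_at probe sets) and none of 17 passed either way. Their largest differences on both days were in Gnl3 (0.50 ± 0.21), Nop56 (0.35 ± 0.22), Nolc1 (0.30 ± 0.21) and Nop16 (0.30 ± 0.21). Of 13 p53 target genes, Trp53inp1 rose by 1.02 ± 0.23, 11 did not pass and 1 was not tested, with 4 up adjusted over the list alone and medians of 0.22 and 0.16. Mdm2 differed by 0.67 ± 0.21, Aen by 0.62 ± 0.21 and Phlda3 by 0.34 ± 0.21. Of 15 interferon and antigen presentation genes 12 were tested and none passed either way, with medians of 0.08 (-0.0077 after quantile normalization) and 0.03. B2m, the light chain of MHC class I, differed by -0.42 ± 0.21, Ifit1 by 0.34 ± 0.21, Bst2 by 0.14 ± 0.21 and Oas1a by 0.08 ± 0.21.

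Genes of glycolysis, hypoxia and cholesterol synthesis had medians below 0 with 4OHT. Of 14 measured glycolysis and hypoxia genes, 5 fell, none rose and 9 did not pass (8 fell adjusted over the list alone), with medians of -0.52 at day 4 and -0.87 at day 6. The phosphofructokinase gene Pfkp fell by 1.42 ± 0.22, the mitophagy receptor gene Bnip3 by 1.52 ± 0.24, Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 1.03 ± 0.21, and the lactate dehydrogenase gene Ldha by 0.91 ± 0.21. Car9, a carbonic anhydrase induced by hypoxia, fell by 0.87 ± 0.21 and was named after its values were seen. Of 4 probe sets of Pdk1 past the level filter, 2 gave the same direction on both days. Gapdh was read only by control probe sets and its 3' probe set was lower by 0.38 and 1.02. Of 10 cholesterol synthesis genes, 5 fell, none rose and 5 did not pass (7 fell adjusted over the list alone), with medians of -0.55 and -1.03. The farnesyl diphosphate synthase gene Fdps fell by 1.22 ± 0.21, Idi1 fell by 1.16 ± 0.21 and the lanosterol synthase gene Lss fell by 0.997 ± 0.21. Sqle, which fell by 0.90 ± 0.24, and Cyp51, which fell by 1.202 ± 0.25, were named after their values were seen, and Mvd (-0.78 ± 0.21, adjusted p = 0.053) did not pass over all genes. The medians below 0 stand on the arrays with the larger 3' minus 5' differences given above for Actb and Gapdh.

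Markers of cells other than epithelium had medians near 0. Of 11 fibroblast and muscle markers 6 were tested and none passed, with medians of 0.05 and 0.02 and with Des at -0.23 ± 0.21, Col1a1 at 0.21 ± 0.21, Dcn at -0.14 ± 0.21 and Acta2 at 0.11 ± 0.21. Of 5 endothelial markers 3 were tested and none passed, with medians of -0.0021 (-0.46 over members past the level filter) and 0.03, Pecam1 at 0.41 ± 0.23 and Cdh5 at -0.23 ± 0.22. Of 10 immune cell markers, with medians of -0.07 and 0.02, only Lyz2 rose (1.31 ± 0.25), a lysozyme gene that is a close copy of the Paneth cell gene Lyz1, while 6 did not pass and 3 were not tested. The other 3 named, Adgre1, Cd4 and Cd8a, differed by -0.14 ± 0.21, 0.11 ± 0.21 and -0.15 ± 0.21. For these 3 lists the counts were the same adjusted over the list alone. Among 11 immediate early and heat shock genes, Jun rose by 0.86 ± 0.21 and Fos fell by 1.05 ± 0.24, both subunits of the AP-1 transcription factor, while 7 did not pass and 2 were not tested (the same counts adjusted over the list alone). The list's medians were 0.17 (-0.066 with the mean of all probe sets) and -0.17. Junb differed by -0.44 ± 0.21 and Zfp36 by -0.50 ± 0.21.

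**Figure D3:**
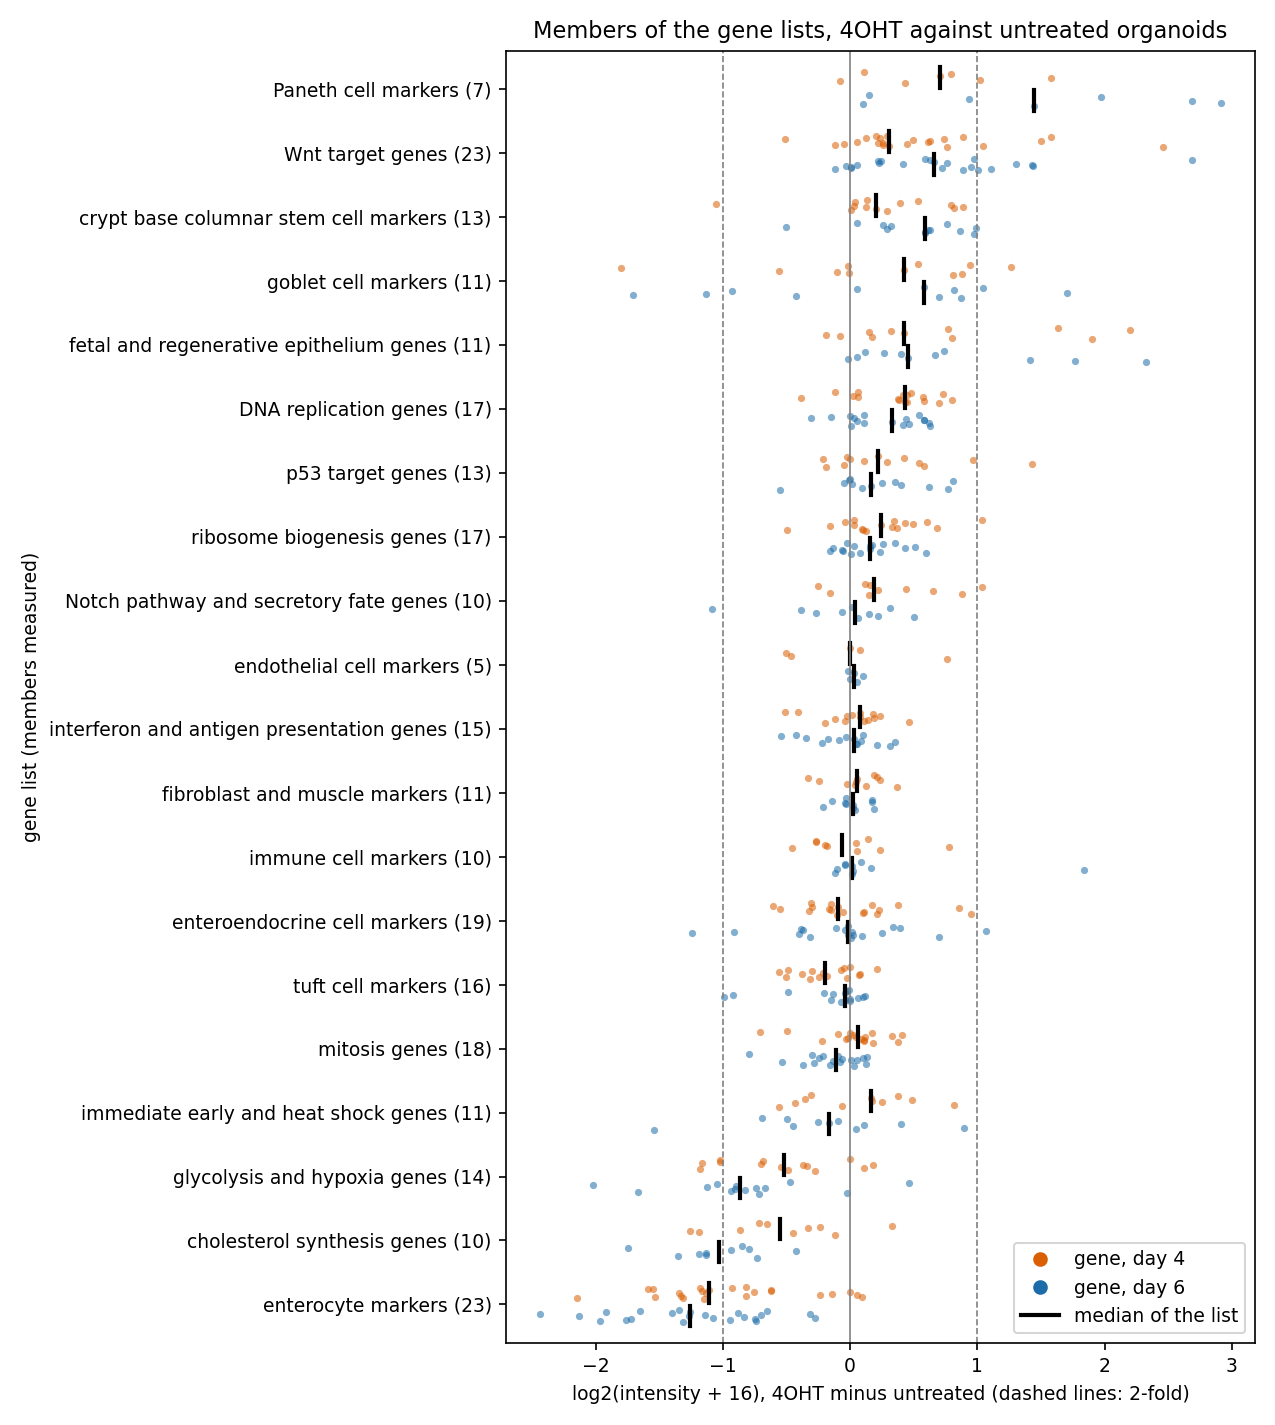
Difference between 4OHT and untreated organoids, log2(intensity + 16), of each measured member of the 20 gene lists at day 4 (orange) and day 6 (blue), with the median of each list as a black bar and 2-fold marked by dashed lines. Medians run from -1.11 and -1.26 in enterocyte markers to 0.71 and 1.45 in Paneth cell markers.

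Taken by day at 2-fold, more genes were lower than higher with 4OHT, a split that turned at day 4 with a threshold of 1.5-fold (1038 higher, 742 lower) or a pseudocount of 1 (437 and 402). At day 4, 132 genes were at least 2-fold higher and 161 lower, and 12 of 23 enterocyte markers and 4 of 14 glycolysis and hypoxia genes were at least 2-fold lower. At day 6, 116 genes were higher and 392 lower, with 14 enterocyte markers, 4 glycolysis and hypoxia genes and 5 of 10 cholesterol synthesis genes at least 2-fold lower. On the same pairs, the spiked hybridization controls differed with 4OHT by -0.38 at day 4 and 0.89 at day 6. The poly-A controls differed by -0.52 and 1.48. Whether less labelled sample RNA on the 4OHT array of day 6 adds to its lower genes was not tested. Across genes, which are not independent replicates, the differences of the 2 days correlated with Pearson's r = 0.407 and Spearman's rho = 0.290, and 58.0% of genes had the same sign. The differences of 531 genes lay at least 1 apart between the days, with 116 more positive and 415 more negative at day 6. Ang4 (1.02 at day 4, 2.91 at day 6) and Dmbt1 (-1.90 and -3.89) were among them, while Nkd1 went from 2.46 to 1.01. Each contrast of a day sets 1 array against 1, so none of these differences has a replicate check and none between the days was tested. After quantile normalization the split was 190 higher and 270 lower at day 4, 138 and 267 at day 6, and 229 and 296 for the genes at least 1 apart; with a pseudocount of 64 the day 4 count was 78 against 293.

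Time in culture was compared within each arm, with the untreated pair as the background for the 4OHT pair. Enterocyte genes were higher at day 6 than at day 4 in both arms, with medians of 1.62 untreated and 1.40 with 4OHT, and 17 and 15 of 23 members at least 2-fold higher. The 3' minus 5' difference of Actb changed from day 4 to day 6 by -1.24 untreated and -1.56 with 4OHT. That of Gapdh changed by -0.56 and -0.87. The day 4 arrays thus had the stronger 3' bias, and its part in the differences over time was not tested. Enpep, a brush border aminopeptidase, was 20.3-fold higher untreated and 21.9-fold with 4OHT, Cyp4f14 12.2-fold and 10.4-fold, and Tmigd1 10.3-fold and 14.7-fold. The zinc finger gene Zfp950 (13.5-fold and 11.0-fold) and the ion channel gene Trpm7 (10.8-fold and 9.90-fold) were also among the 5 largest differences upward. Vegfa, the angiogenic growth factor gene, was 12.9-fold lower at day 6 untreated and 4.61-fold lower with 4OHT, and Nfia, Rapgef6, Zc3h15 and the cornified envelope gene Sprr1a were lower by 4.51-fold to 9.75-fold untreated and 3.81-fold to 4.51-fold with 4OHT. On the probe sets used, all 10 kept their direction after quantile normalization. For Trpm7, Vegfa, Nfia, Rapgef6 and Zc3h15, other probe sets past the level filter did not all give that direction in both arms: another probe set of Vegfa was 0.28 higher at day 6 untreated and 0.90 higher with 4OHT.

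Mitosis genes were higher at day 6 by a median of 1.12 untreated and 1.07 with 4OHT, DNA replication genes by 1.25 and 1.15, and stem cell markers by 1.18 and 1.87. With the mean of all probe sets of a gene the stem cell medians were 0.56 and 0.98. Olfm4, a marker of stem cells named after its values were seen, was higher by 2.30 and 2.88. Paneth cell markers had medians of -0.97 untreated and -0.26 with 4OHT, and genes of fetal and regenerating epithelium -0.48 and -0.42. Ang4 was 4.78-fold lower at day 6 untreated and 1.29-fold lower with 4OHT, the latter turning to 0.045 higher on the log2 scale without the _x_at and _s_at probe sets. The medians of the remaining lists, untreated and with 4OHT, were 0.83 and 0.57 for ribosome biogenesis, 0.78 and 0.54 for cholesterol synthesis, 0.76 and 0.40 for the Notch pathway, and 0.45 and 0.21 for immediate early and heat shock genes. They were -0.03 (0.075 after median centring) and -0.49 for glycolysis and hypoxia, and -0.22 (0.031 with the mean of all probe sets) and -0.16 for Wnt targets. For p53 targets they were -0.27 (0.031 with the mean of all probe sets) and -0.13, and for interferon genes -0.03 (0.074 after median centring) and -0.10. For goblet cell markers they were -0.10 (0.10 without the _x_at and _s_at probe sets) and 0.16. They were -0.12 and -0.24 for enteroendocrine, -0.25 and -0.12 for tuft, -0.33 and -0.45 for fibroblast and muscle, -0.48 and -0.24 for immune, and -0.50 and -0.24 for endothelial cell markers.

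In the untreated pair 3178 genes were at least 2-fold higher and 698 lower at day 6, and in the 4OHT pair 2160 and 355. The differences of the arms, which share no array, correlated across genes with r = 0.876 and rho = 0.872. These splits depend on the scaling between the days, which is not known: after quantile normalization, which gives all arrays the same distribution, they were 1570 higher and 1635 lower untreated and 1231 and 1030 with 4OHT, and after median centring 3601 and 520 untreated and 2518 and 229 with 4OHT. After quantile normalization the medians of mitosis genes became 0.57 and 0.62, of DNA replication genes 0.80 and 0.68, of stem cell markers 0.49 and 1.44, of ribosome biogenesis genes 0.27 and 0.12, of cholesterol synthesis genes 0.11 and 0.07, of goblet cell markers -0.56 and -0.27, of glycolysis and hypoxia genes -0.60 and -0.80, of p53 targets -0.66 and -0.56, of immediate early and heat shock genes 0.13 and -0.12, and of Wnt targets -0.35 and -0.26. Over time 16 of the 20 list medians untreated and 17 with 4OHT turned or moved by over 1.5 times under at least 1 setting.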

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

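The tests of labelled RNA, of the spread of values and of the day 6 part of the 3' bias were chosen only after the results they bear on had been seen.

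The medians of 4 lists had opposite signs on the 2 days with 4OHT, and the differences between the days were not tested. The day 6 minus day 4 difference of medians was -0.33 for immediate early and heat shock genes (0.17 to -0.17), -0.18 for mitosis genes (0.06 to -0.11), 0.083 for immune cell markers (-0.07 to 0.02) and 0.034 for endothelial markers (-0.0021 to 0.03). After quantile normalization the signs were alike for mitosis genes (-0.012 and -0.0042) and endothelial markers (0.0050 and 0.033). With the mean of all probe sets they were alike for immediate early and heat shock genes (-0.066 and -0.17). Goblet cell markers differed in sign between the arms over time, -0.10 untreated and 0.16 with 4OHT, a difference of 0.26 that was not tested either. The signs were alike after median centring (0.0063 and 0.26) and after quantile normalization (-0.56 and -0.27). They were alike too without the _x_at and _s_at probe sets (0.10 and 0.16). Outside the gene table, the hybridization controls at day 6 were 0.89 brighter on the 4OHT array than on the untreated one (10.5 against 9.59), and the poly-A controls 1.48 brighter (9.84 against 8.36). Among probe sets that name no gene, 4 were at least 2-fold higher and 4 at least 2-fold lower with 4OHT on both days.

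More genes were higher than lower at day 6 against day 4, 3178 against 698 in the untreated pair. A candidate explanation is less labelled sample RNA relative to the spiked controls on the day 4 arrays: the 42 spiked control probe sets were brighter at day 4 by a median of 2.85 untreated and 1.14 with 4OHT, in keeping with it. It was found on the same arrays. A change of the organoids with time in culture stays open and was not tested, since each day and arm has 1 array.

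Glycolysis and cholesterol synthesis genes were lower with 4OHT, with 19 of 24 members below 0 on both days. The median of the 24 was -0.59 at day 4 and -0.77 at day 6 after quantile normalization, so it stayed below 0 with like distributions of values. The arrays of a day had nearly the same percentiles as deposited, so this setting could change the median only a little. It therefore does not decide on scaling between arrays, nor on whether unequal labelled RNA adds to the difference. Stronger 3' bias on the 4OHT arrays cannot be told apart at day 4, where the least lowered probe set of each of 14 members with several gave a median of -0.17. At day 6 that median was -0.61 (bootstrap SE over members 0.17), so these members were lower even on their least lowered probe set. The distance of the probe sets from the 3' end was not used, and all of a gene may lie away from it. The test therefore cannot exclude 3' bias at day 6 either. A response to recombined Apc stays open, as does one to 4OHT itself, and neither was tested because no 4OHT arm without the floxed allele is among the arrays.

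More genes passed 2-fold with 4OHT at day 6 than at day 4, 508 against 293, a ratio of 1.73. The day 4 arrays hold a narrower spread of values, and after quantile normalization the ratio was 0.88, so the difference in spread may account for the excess. The excess also depends on the pseudocount and the threshold: with a pseudocount of 1 the counts were 839 at day 4 and 737 at day 6, with 64 they were 78 and 275, and at 1.5-fold they were 1780 on each day. Whether the response grew with time in culture stays open and was not tested.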

How the results depend on the processing

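Leaving out _x_at and _s_at probe sets was chosen after seeing the data; the other alternatives were fixed before. Median centring kept the total of each count of genes within 1.5 times, but 229 and not 355 genes were lower over time with 4OHT. No named gene turned its direction under centring, quantile normalization or other probe sets where it had passed 2-fold on the contrast it was named for, although 105 values moved. Smaller differences did turn: with 4OHT in 4 named genes at day 4 and 3 at day 6 with the mean of probe sets (Cdt1 at day 4 to -0.046), and over time, after quantile normalization, in 9 of 103 named genes untreated and 6 with 4OHT. These hold the probe set of each gene fixed, which was decided after the results were seen. Chosen anew after quantile normalization, it was another one for Fabp1 and for Trpm7, which turned over time (-0.93 untreated, -0.56 with 4OHT), as then did 10 named genes in all untreated and 8 with 4OHT, and 458 genes passed 2-fold at day 4. Counts on the fold rule did not depend on the level filter by construction where it was dropped, since no gene under it reached 2-fold. For all results below the cause was not tested. The level filter left 5001 genes out of the test. With a pseudocount of 1, 839 genes passed 2-fold at day 4 (293 as reported), 3965 for time with 4OHT (2515), 202 on both days (132) and 1239 for the difference between days (531). With 64 the counts were 78 at day 4, 275 at day 6, 2197 and 1258 for time (untreated, 4OHT), 43 on both days and 169 for the difference between days. With the mean of all probe sets they were 160, 337, 2335 and 1369, and 259 for the difference between days, and with quantile normalization 460 at day 4. At 1.5-fold they were 1780 on each day, 7276 and 5705 for time, 492 on both days and 2569 for the difference, and at 3-fold 34, 126, 1435, 771, 19 and 52 in the same order. Limma's additive test, with 425 genes as reported, called 0 without the level filter (2050 at an unadjusted p under 0.05), 232 with the filter on the mean, 47 with a pseudocount of 1, 0 with 64 (1644 unadjusted), and 0 without the day term (70 unadjusted). Its prior degrees of freedom were 15.2 as reported, 3.30 without the filter, 6.19 with a pseudocount of 1 and 3.57 with 64. Leaving out each array, with no day term and the lone array assumed to vary like the other arm, gave 0 to 65 genes: 65 without untreated day 4, 0 without 4OHT day 4, 0 without untreated day 6 and 2 without 4OHT day 6. Other settings gave 295 (quantile) to 613 (adjusted p of 0.1).

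Of the 20 list medians, 15 at day 4, 12 at day 6, 16 over time untreated and 17 over time with 4OHT turned or moved by over 1.5 times under at least 1 setting. The medians that moved beyond their bootstrap SE were as follows with 4OHT, with Wnt targets over time added. Wnt targets were at 0.47 at day 4 over members past the level filter, 0.38 at day 6 with the mean of probe sets, and reversed over time untreated to 0.031 with the mean of probe sets and 0.046 without _x_at and _s_at probe sets. With the mean of probe sets, enterocyte markers were at -0.93, mitosis genes at -0.0091, DNA replication genes at 0.16 and immediate early genes at -0.066 at day 4, and glycolysis genes at -0.72 at day 6. With quantile normalization, mitosis genes were at -0.012 and -0.0042 on the days in turn, interferon genes at -0.0077 at day 4 and glycolysis genes at -0.73 at day 6. Without _x_at and _s_at probe sets, ribosome biogenesis genes were at 0.076 at day 6 and glycolysis genes at -0.68 at day 4. Endothelial markers past the level filter were at -0.46 at day 4.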

Other observations

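Families of drug-metabolizing enzymes were gathered by their gene symbols after the data had been seen. They were cytochrome P450 families 1 to 4, carboxylesterases, sulfotransferases, UDP-glucuronosyltransferases, glutathione S-transferases and alcohol and aldehyde dehydrogenases. All 89 genes counted lay past the level filter, so any family member under it is not in these shares. By limma's additive test 34 fell, 1 rose and 54 did not pass. The medians were -0.44 at day 4 and -0.75 at day 6 (-0.57 and -0.62 after quantile normalization). Among 28 cytochrome P450 genes 10 fell, with Cyp2c65 lower by 1.34 at day 4 and 2.54 at day 6, and 1 rose, Cyp2e1, which was higher by 1.30 and 0.93. Of 10 carboxylesterases 6 fell, and of 6 UDP-glucuronosyltransferases 4, including Ugt2b5, which differed by -0.19 at day 4 and -3.96 at day 6. Of 20 glutathione S-transferases 5 fell, with a median of -0.11 at day 4, at the 2.69th percentile of random lists, and of 19 alcohol and aldehyde dehydrogenases 6 fell. The enterocyte markers, with medians of -1.11 and -1.26, and the larger 3' minus 5' differences of Actb (by 0.94 and 0.62) stand on the same 4OHT arrays, and Cyp3a11 belongs to both sets of genes. Some genes of the families are the ones that led to the choice of families, so their counts are not independent of it. The families were higher at day 6 by a median of 0.98 in the untreated pair and 0.55 in the 4OHT pair.

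The lower glycolysis and hypoxia genes led to the hypothesis that targets of the hypoxia-inducible factors (HIF) are lower in general with 4OHT. Of those 14 genes, 10 were lower on both days and 0 were higher on both. Vegfa, one of the 14, was mixed: it differed by -1.02 at day 4 and 0.46 at day 6. The hypothesis was tested on 15 measured HIF targets that stand in none of the fixed lists, with the prediction written before their values were seen. Their median was -0.28 at day 4 and -0.54 at day 6, at the 0.12th percentile of random lists of like level at day 4 and below all 10000 at day 6, which is consistent with the hypothesis. None of the 12 that were tested passed limma's additive test alone, the percentiles describe these arrays only, and the 3' bias of the 4OHT arrays applies to these genes too.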
